A study of Mus musculus with 4 samples.

How the data were processed

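RNA of 4 MEF samples was measured on one-colour Agilent circRNA arrays, with 2 Rnasek KO and 2 control samples grouped by their titles. Per the labels, enriched circular RNA was amplified by random priming and labelled with Cy3. The way circular RNA was enriched is not given in the sources used here. The authors deposited the scanner output of each array, and per the submitters' processing notes the images were read with Agilent Feature Extraction 11.0.1.1. The intensity of each spot is, per the file headers, the processed green signal on a linear scale, with background subtracted and no scaling between arrays. The flags for spots well above background, saturated spots and outlier spots are, per the file headers, other outputs of Feature Extraction. The authors also deposited a value table, and its values lie on what appears to be a log2 scale, since each column tracked the log2 intensity of its own array best (Pearson r = 0.909 to 0.963 across probes). Its columns had medians of 5.30, 5.30, 5.30 and 5.25, so a normalization between arrays is inferred from the values and not stated. The table lists 14218 of the 14236 circRNA probes and 18 were not listed.

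Spots of one probe were averaged, as was the case for the accession probes with 10 spots each. The log2 processed signal was scaled by subtracting each array's 75th percentile over its non-control probes. circRNA probes were tested if they were well above background on both arrays of at least 1 group, which left 12181 after 2035 dim probes and 20 with an outlier spot were set aside. No non-control spot was saturated (0 on each array). Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, KO minus control), with Benjamini-Hochberg adjustment over the circRNAs tested and a threshold of 0.05. The design, the thresholds, the rule for named items and most alternatives were fixed before the data were examined. By that rule the named circRNAs are the 10 with the largest increase and the 10 with the largest decrease among those that passed with no overlap between the groups. They were ranked among probes well above background on all arrays, a narrowing that the rule did not spell out, since values at the floor have no order. Of them, 4 are given by identifier. Where neither array of a group was well above background, a fold is printed as "at least N-fold", the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal, on normalized log2 values. Medians over such circRNAs are also given with these at their bound, a choice made after the data were seen.

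Accession probes were tested in one fit with the circRNA probes and adjusted among themselves. Control probes were tested in the same fit and adjusted within each kind. Symbols came from a RefSeq gene table of assembly GRCm38.p6 by accession without version. Of 50 accessions, 44 matched 1 symbol and 6 matched none. The file headers name build mm9, so no coordinates are given. Every accession probe with a symbol that passed is named, a choice made after the values were seen.

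The number of arrays sets the precision. The test was checked on simulated data with the spread of the 12181 circRNAs of this comparison. With 200 circRNAs changed, it recovered 0% of changes of 1 log2 unit, 1.49% of changes of 2 and 69.7% of changes of 4. With 8000 changed, it recovered 63.0%, 89.7% and 98.4%, and 2.13% of the calls were false. The simulated noise was independent between probes, with no scan effect and no trend with signal. The share of false calls in the simulation thus cannot be carried over to the calls made here. Nor can the recovery, since each simulated circRNA took as its true SD the SD estimated from 2 arrays per group. Such estimates scatter more than true SDs, which leaves eBayes less to share between probes, so the recovery may be too low. In the simulation, a call of a small change depended on how many other circRNAs changed.

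The alternatives tried were quantile, median and no scaling, cyclic loess, normexp background correction (offset 50) with either the 75th percentile or quantile normalization, the deposited value table, no filter and a filter for signal on all arrays, eBayes with trend and robust settings, the replicate number as a block, and each array left out in turn. Normexp was run on the median spot signal, and the unscaled shift was also taken on that signal less its background. The lists of host genes, the classes of circRNA and a circRNA of Rnasek were planned but not analysed here, since the files do not pair circRNA identifiers with genes. Scan and group coincide, so no fit with the scan as a block could be made. Permutation tests and figures were made in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3.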

Results

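Circular RNA was profiled on 4 one-colour arrays in mouse embryonic fibroblasts (MEFs), primary cells isolated from embryos of day 12.5 to 13.5. Rnasek encodes RNase κ, an endoribonuclease, an enzyme that cleaves RNA within the strand. The gene was deleted in MEFs that carried a floxed Rnasek gene together with UBC-CreERT2, a Cre recombinase that becomes active in the presence of 4-hydroxytamoxifen (Rnasek KO, n = 2). Floxed MEFs without the recombinase served as controls (n = 2), and both genotypes received 2 µM 4-hydroxytamoxifen for 4 days. The groups thus differ in the active recombinase as well as in Rnasek, and the design cannot separate the effects of each. The arrays carried 14236 probes for circular RNAs (circRNAs), each known in the files by an identifier alone, and 50 probes with a transcript accession, of which 44 could be given a gene symbol. The titles call the replicates of each group biological, but the labels do not say whether they came from separate embryos or cultures, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

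The KO arrays gave measurable signal for more circRNAs than the control arrays. A circRNA signal well above background was found for 84.3% of the probes in Rnasek KO 1 and 89.2% in Rnasek KO 2, compared with 56.9% in control 1 and 57.3% in control 2. The median processed signal of all circRNA probes was 29.2 and 34.8 intensity units on the KO arrays and 7.38 and 7.28 on the control arrays. The 99th percentile of the signal was lower on the KO arrays, at 2414 and 3497 against 7411 and 4671 on the control arrays. The very brightest probes were again on the KO arrays, with 16 and 26 probes over a log2 signal of 16, against 0 and 2 on the control arrays. Negative control spots had a net signal of 15.0 and 14.9 on the KO arrays and 4.36 and 4.02 on the control arrays. Across circRNA probes, which are not independent replicates, log2 signals correlated with r = 0.961 between the KO arrays and r = 0.984 between the control arrays, and with r = 0.614 to 0.787 between arrays of different groups.

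**Figure D1:**
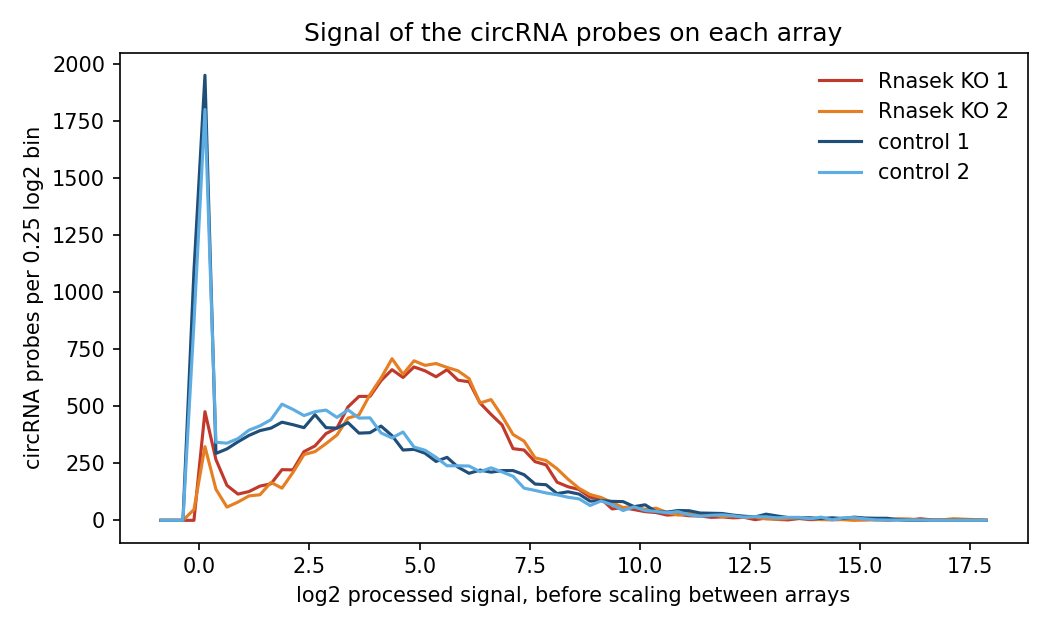
Number of circRNA probes (y axis) at each log2 processed signal before scaling between arrays (x axis, bins of 0.25), with 1 line per array. The control arrays hold more probes at the floor near a log2 signal of 0, while the median signal was 29.2 and 34.8 on the KO arrays and 7.38 and 7.28 on the control arrays.

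The first comparison asked which circRNAs differ in level between Rnasek KO and control MEFs. Among circRNAs measured on all 4 arrays, ASCRP4009879 was the most increased in KO MEFs, with signals of 11942 and 8034 on the KO arrays and 10.6 and 16.6 on the control arrays (log2 change 8.32 ± 0.45 SE, n = 2 per group, limma adjusted p = 0.000186). ASCRP4009179 followed, with a log2 change of 7.01 ± 0.40 (SE). The most decreased circRNA was ASCRP4006632, with signals of 76.6 and 354 on the KO arrays and 7151 and 3353 on the control arrays (log2 change −6.11 ± 0.64 SE, n = 2 per group, limma adjusted p = 0.000365), followed by ASCRP4006290 with a log2 change of −5.84 ± 0.35 (SE). The 10 most increased circRNAs had log2 changes of 5.58 to 8.32, and the 10 most decreased had changes of −5.33 to −6.11. Over 8 scalings between arrays, including the deposited value table, the change ranged from 6.62 to 10.34 for ASCRP4009879, 4.80 to 8.36 for ASCRP4009179, −6.81 to −3.60 for ASCRP4006632 and −6.54 to −2.52 for ASCRP4006290. ASCRP4006290 was more decreased than ASCRP4006632 after quantile normalization (−6.01 against −4.65) and cyclic loess (−5.26 against −3.60), so their order depends on the scaling. The files do not pair circRNA identifiers with host genes, so neither the host genes of these circRNAs nor a circRNA of Rnasek itself can be named, and the deletion could not be checked on the arrays.

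Of 12181 circRNAs tested, 9229 (75.8%) differed between the groups at a limma adjusted p under 0.05, with 5377 higher and 3852 lower in KO MEFs. Among the circRNAs well above background on all arrays, 1309 of the higher and 3233 of the lower circRNAs changed by more than 2-fold. At an unadjusted p under 0.05 and a change of at least 1.5-fold, 9456 circRNAs were counted, where chance would give at most 609 at that p. This count was 4796 after normexp with the 75th percentile and 4057 after normexp with quantile normalization. For 3470 of the 9456 neither control array was well above background, so that their fold is against a background level. The KO and control arrays did not overlap for 91.0% of the circRNAs tested, against 33.3% by chance with 2 arrays per group. The 91.0% includes circRNAs kept through 1 group alone, and among those well above background on all arrays it was 88.3%. Many of the array's own control probes differed too (28 of 41 called, adjusted within each kind), so such a share need not be particular to circRNAs.

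Among the 7396 circRNAs well above background on all arrays, a set that leaves out circRNAs too dim on the control arrays, 1454 were higher in KO MEFs, 3568 were lower and 2374 did not pass, with a median log2 change of −0.75. Another 3761 circRNAs were well above background on both KO arrays and on neither control array, so their direction is set by this selection and their control level is only a bound. They hold 3430 of the 5377 circRNAs called higher. By the bound, 2970 of the 3761 were higher in KO MEFs, 1850 of them at least 2-fold. These bounds are for the 75th percentile scaling alone, and after normexp with the 75th percentile 1801 of all circRNAs tested were called higher. The opposite case, well above background on both control arrays and neither KO array, held for 45 circRNAs, with a median of at least 3.52-fold, and 979 were detected on only some arrays of a group.

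The change went with the signal. In the dimmest decile of the circRNAs tested, 1090 were higher and 36 lower in KO MEFs, and the median log2 change was 2.00. However, 1211 of its 1219 circRNAs were measured in 1 group alone, and with these at their bound the median was −0.08 (0.79 in the next decile). In the brightest decile, 101 were higher and 980 lower, and the median log2 change was −2.27. The split between higher and lower circRNAs depended on the scaling between arrays. After scaling to the 75th percentile, as above, 58.3% of the circRNAs that differed were higher in KO MEFs, and the share was 85.3% without scaling, 54.0% after cyclic loess, 46.8% after quantile normalization, 45.2% after median scaling, 43.7% in the deposited value table, 40.1% after normexp background correction with quantile normalization and 24.8% after normexp with the 75th percentile. The set of calls changed too. Of the 9229 circRNAs, 87.2% were called in the same direction after median scaling, but 59.4% after normexp with the 75th percentile. In that setting 495 were called in the opposite direction. The share kept was 61.7% after normexp with quantile normalization (28 opposite). In the deposited value table it was 69.0% of the 9217 tested there (16 opposite). Called in the same direction under all 8 scalings were 1460 higher and 872 lower circRNAs, among them the 4 named above. Of these, 698 of the higher and 764 of the lower were well above background on all arrays. The array's own control probes that passed the filter (n = 41) had a median absolute log2 change of 1.28, from 0.34 for the DCP probes to 2.44 for the MM9NEGATIVE probes, compared with 1.74 for the circRNAs. Only 5 of the 15 MM9NEGATIVE probes passed. A filter for signal in at least 1 group favours dim probes that differ, so their median may be raised by it. Not counted among these, the 13 AS_circRNA_control probes had a median of 0.58 and the 15 CUST probes a median of 2.11. The files do not state what the MM9NEGATIVE, AS_circRNA_control and CUST probes target. KO arrays shared one scan and control arrays another, so batch and group cannot be told apart for any of these differences.

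**Figure D2:**
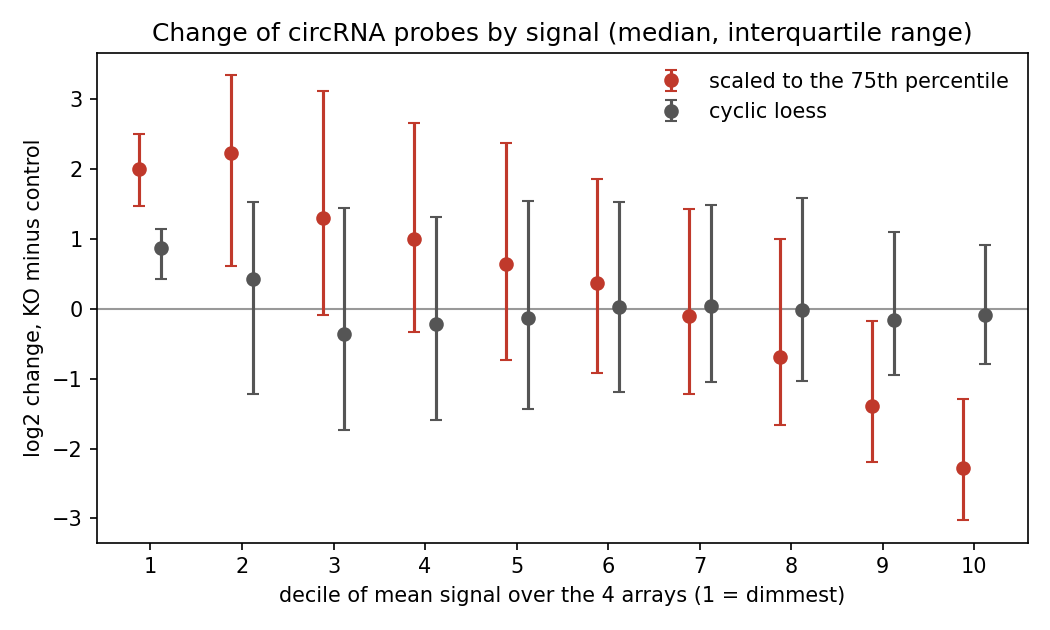
Log2 change of the circRNA probes, KO minus control (y axis), by decile of mean signal over the 4 arrays (x axis, 1 is the dimmest), with points at the median and bars over the interquartile range. After scaling to the 75th percentile (red) the median goes from 2.00 in the dimmest decile to −2.27 in the brightest, and after cyclic loess (grey) it is 0.87 and −0.08 there. In the dimmest decile most control values lie at background, and the median with these at their bound is also −0.08.

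The second comparison asked whether the level of all circRNAs together differed between the genotypes before any scaling between arrays. The median log2 signal of the 12181 circRNAs tested was 5.37 ± 0.16 (SD, n = 2) in KO MEFs and 3.46 ± 0.07 (SD, n = 2) in control MEFs, and the median change per circRNA was 1.65 on the log2 scale, or 3.14-fold. An exact two-sided permutation test of the array medians gave p = 0.333, which is the smallest p that 2 arrays per group allow. With circRNAs measured in 1 group alone at their bound, the median change was 1.21 before scaling and −0.0025 after scaling to the 75th percentile. Without bounds it was 0.44 after scaling to the 75th percentile, −0.13 after quantile normalization and −0.26 after median scaling. Over the circRNAs well above background on all arrays, the unscaled median change was 0.46, and on normexp values of all circRNAs tested it was 0.33. Negative control spots also had a higher net signal on the KO arrays (15.0 and 14.9) than on the control arrays (4.36 and 4.02). The unscaled shift therefore cannot be told apart from differences in input, labelling or scanning.

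Probes with a transcript accession formed a further comparison, chosen after the data had been seen. These are the probes that carry gene names, and the files do not say whether they read linear or circular transcripts. Of the 50, 43 could be tested, and 15 were higher in KO MEFs, 19 were lower and 9 did not pass (limma, adjusted over these 43 probes). Actb, which encodes the cytoskeletal protein β-actin, had the largest increase, with signals of 7762 and 45972 on the KO arrays and 10.6 and 41.4 on the control arrays (log2 change 8.61 ± 0.92 SE, n = 2 per group, limma adjusted p = 0.000293). Ppara, which encodes a nuclear receptor that controls fatty acid oxidation, had the largest decrease, with signals of 7.28 and 7.33 on the KO arrays and 219 and 170 on the control arrays (log2 change −5.93 ± 0.30 SE, n = 2 per group, limma adjusted p = 9.53e-06).

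Among the probes that were higher in KO MEFs, Gpi1, the glycolytic enzyme glucose-6-phosphate isomerase, changed by 3.17 ± 0.31 (log2, SE) and Lhfp by 2.58 ± 0.60. H2-Q7, a non-classical class I histocompatibility gene, changed by 4.32 ± 0.48, but its family members are alike in sequence and the gene is therefore uncertain. Taf1a, a subunit of the RNA polymerase I factor SL1, changed by 1.29 ± 0.34 and the spermatogenesis-associated gene Spats1 by 0.97 ± 0.37. Spats1 lost its call with the replicate number as a block and without Rnasek KO 2 (0.57), control 1 (1.05) or control 2 (0.89), and its change was 1.37 without Rnasek KO 1. For 8 of the 15 probes neither control array was well above background, so the change is a bound: Uhrf1bp1l was at least 15.6-fold higher in KO MEFs, the nuclear pore gene Nup50 at least 6.12-fold, the ribosomal protein gene Rps4l, which has close paralogs and is likewise uncertain, at least 5.29-fold, Carhsp1 at least 1.83-fold, the centrosomal gene Cep41 at least 1.66-fold and the glutathione S-transferase gene Gsta4 at least 1.12-fold. Bambi, a decoy receptor of TGF-β signalling, and Trp53rka passed the test but their bound lay under 1-fold, so no fold is given. These bounds too are for the 75th percentile scaling alone. After normexp with the 75th percentile the log2 change was 1.45 for Uhrf1bp1l, 0.60 for Nup50 and 0.36 for Rps4l. For Actb the arrays of each group differed widely (SD 1.64 for KO and 1.61 for control on the log2 scale, n = 2 each), though both KO arrays lay above both control arrays.

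Among the probes that were lower in KO MEFs, all 19 were well above background on all arrays. They included the olfactory receptor genes Olfr166 (log2 change −3.26 ± 0.41 SE) and Olfr1307 (−1.55 ± 0.36), the T cell cytokine Il2 (−2.42 ± 0.33), the B cell chaperone Mzb1 (−2.12 ± 0.34), the neuroendocrine granin Chgb (−1.54 ± 0.31) and the developmental transcription factors Lhx1 (−1.72 ± 0.30) and Ascl1 (−1.27 ± 0.30). All of these are among the genes classed below as tissue-restricted, and whether their probes read the named transcripts in MEFs was not tested. Their values are therefore probe signals, not evidence that MEFs express these genes. Gamt, an enzyme of creatine synthesis, changed by −2.98 ± 0.46, the peroxisomal gene Pex11a by −2.73 ± 0.36 and the lipid carrier Apoe by −1.09 ± 0.31. The call of Apoe was lost without Rnasek KO 1 (−0.88) and without control 1 (−1.02). The annexin Anxa8 changed by −3.03 ± 0.45, the NADPH oxidase Duox1 by −2.92 ± 0.35, Alkbh4 by −2.27 ± 0.39, Tm9sf1 by −1.37 ± 0.31 and the hyaluronidase gene Hyal3 by −1.33 ± 0.31. After cyclic loess the change of Pex11a was −0.05, so it depends on the scaling, and without scaling the change was −0.12 for Hyal3, −0.16 for Tm9sf1, −0.33 for Chgb and −0.34 for Olfr1307.

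The probes that did not pass belonged to E2f1, Dnajc11, Cpt1a, Rab5a, Gsdmd, Prdx2, Hspb7, Acaa2 and Atg3. Prdx2, a peroxiredoxin with signals of 156 and 183 on the KO arrays and 97.7 and 70.0 on the control arrays, had a log2 change of −0.18 ± 0.30 (SE) after scaling, and Gsdmd, the pore-forming gasdermin D, had a change of −0.05 ± 0.30. Tyr, Cav2, Kcnn2, Mbp and Gabrg1 were not well above background on any array. Probes of 19 genes expressed in most tissues, a class set after the values were seen, changed by 3.05 log2 units more on average than probes of 11 tissue-restricted genes when 9 of the 19, measured on the KO arrays alone, were set at their bound (means 1.04 and −2.01, two-sided permutation test, p = 0.00018). The classes hold Actb and Ppara, the probes with the largest changes, and were set with these values known, so the test is no independent support. Called higher in KO MEFs under all 7 scalings tried on these probes were Actb, Uhrf1bp1l, Nup50, H2-Q7, Gpi1, Rps4l, Lhfp and 1 probe without a symbol, and called lower under all 7 were Ppara, Olfr166, Duox1 and Il2. Their size depended on the scaling: the change ranged from 7.24 to 10.76 for Actb, 2.18 to 5.53 for H2-Q7, 1.78 to 4.39 for Gpi1 and 1.32 to 3.79 for Lhfp. It ranged from −6.64 to −2.19 for Ppara, −3.96 to −1.28 for Olfr166, −3.62 to −0.90 for Duox1 and −3.13 to −0.91 for Il2. The direction flipped under at least 1 scaling for Gsta4, Cep41, Bambi, Trp53rka, Carhsp1, Apoe, Ascl1 and Lhx1. Of these, Bambi and Trp53rka (normexp with the 75th percentile) and Ascl1 (cyclic loess) were called in the opposite direction. For the remaining named genes that passed, the direction was kept but not the call under every scaling.

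**Figure D3:**
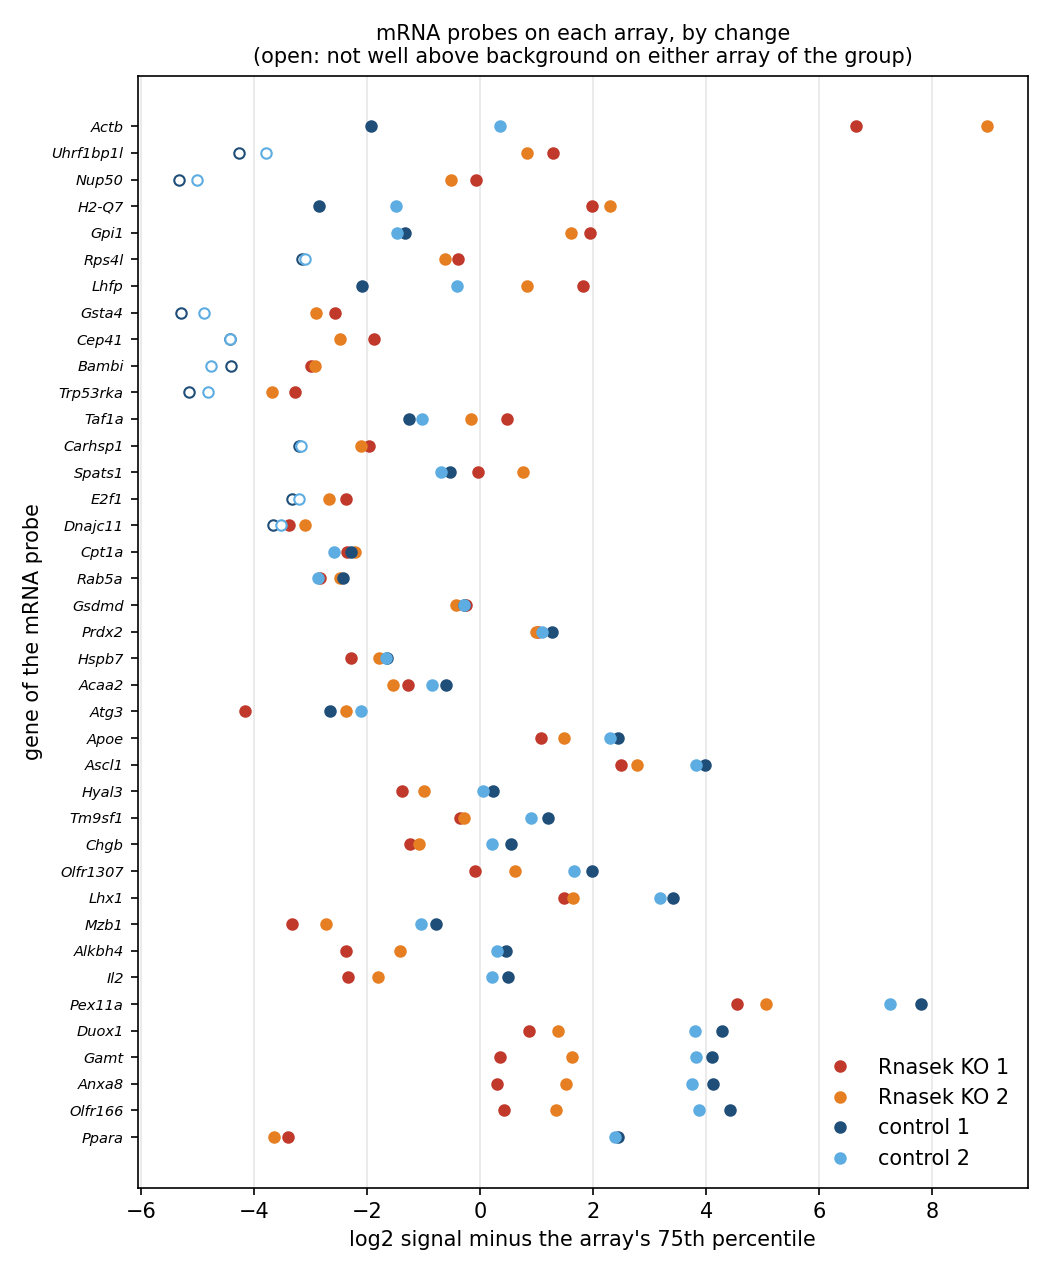
Log2 signal minus the array's 75th percentile (x axis) of each named mRNA probe (y axis, ordered by change), with 1 point per array and open points where neither array of the group was well above background. Actb, at the top, had signals of 7762 and 45972 on the KO arrays and 10.6 and 41.4 on the control arrays, and Ppara, at the bottom, 7.28 and 7.33 against 219 and 170, while from Gsta4 to Carhsp1 and from Apoe to Lhx1 several genes changed direction under another scaling.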

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

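In this part the test of cyclic loess was fixed before its result was seen, and the tests on control probes, scans, expression classes and unscaled signals were chosen after. The split of control probes by kind and the use of bounds came after the values of these tests were seen.

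Signal above the control arrays also appeared on probes outside the circRNA comparison. The strongest of each kind that was higher on the KO arrays was the Actb probe A_51_P173760 among the accession probes (log2 change 8.61), CUST_10_PI419532418 among the custom probes (7.03), MM9NEGATIVE017 (3.17, well above background on 1 of the 2 control arrays) and the spike-in probe E1A_r60_a107 (1.84). On neither control array were the quality probe eQC-42 and DCP_1_1 well above background, and they were at least 3.63-fold and at least 1.67-fold higher on the KO arrays. Over 7 scalings the change ranged from 5.44 to 8.83 for CUST_10_PI419532418, from 0.75 to 4.38 for MM9NEGATIVE017 and from 0.29 to 3.05 for E1A_r60_a107, while after normexp with the 75th percentile the measured difference was 0.15 for eQC-42 and negative (−0.20) for DCP_1_1, and their bounds are for the 75th percentile scaling alone. The strongest in the opposite direction were CUST_12_PI419532418 (−4.43), AS_circRNA_control3000011 (−3.50), ETG09_35454 (−3.17), DCP_20_9 (−2.86) and E1A_r60_3 (−2.10), together with MM9NEGATIVE001, which was on neither KO array well above background and at least 3.65-fold lower there. All 6 were lower under all 7 scalings, MM9NEGATIVE001 with a measured difference from −4.41 to −0.39. Of the ETG probes 0 were higher and 6 lower, and of the DCP probes 2 were higher and 6 lower (limma, adjusted p under 0.05). The DCP calls followed the probe names, since the higher probes were DCP_1_1 and DCP_1_2 and all lower ones had names that begin with DCP_20, so they may not be independent.

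The first pattern is that 75.8% of the circRNAs differed between the groups. A trend of the change with signal level is argued against as the whole cause, since 63.8% of the 9229 circRNAs were still called in the same direction after cyclic loess, although 95 were called in the opposite direction (63.6% kept of the 5022 called circRNAs well above background on all arrays). Cyclic loess reduced the trend but left median changes from 0.87 in the dimmest decile to −0.36 in decile 3, against −0.08 in the brightest. Some calls of dim circRNAs may thus still follow the signal level. Whether part of the difference is signal that is not circular RNA of the cells stays open. Of 41 control probes (E1A_r60, eQC, DCP, ETG and MM9NEGATIVE) 28 were called. They were adjusted within each kind, so this share cannot be set directly against that of the circRNAs. The median absolute change of the 41 was 1.28 (bootstrap 95% interval 1.04 to 1.78) against 1.74 for the circRNAs, or 1.25 against 1.35 where all arrays were well above background. The interval treats the probes as independent, although many share a name stem and changed alike, so it may be too narrow. The kinds also went apart, from 0.34 for DCP to 2.44 for MM9NEGATIVE. With the 13 AS_circRNA_control probes added the median was 1.16, while the 15 CUST probes, also left out, had a median of 2.11. The scan cannot be told apart from the genotype, since 0 scans hold both groups.

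The second pattern is that accession probes such as Actb were far brighter on the KO arrays while others such as Ppara were dimmer. The overall brightness of the arrays is argued against, since on unscaled signals 25% of the 28 probes called went against the rest (21 higher, 7 lower, exact 95% binomial interval 10.7% to 44.9%). A candidate explanation for part of it is that more linear RNA was left in the KO preparations: with 9 of 19 probes of broadly expressed genes set at their bound, these changed by 3.05 log2 units more on average than 11 probes of tissue-restricted genes (means 1.04 and −2.01, two-sided permutation test, p = 0.00018), and the 8 broad probes well above background on all arrays by 3.62 (exact permutation p = 0.00733) or 3.50 after cyclic loess (exact permutation p = 0.0209). Against it, only 4 of the 8 broad probes were higher before cyclic loess (Actb 8.61, H2-Q7 4.32, Gpi1 3.17 and Taf1a 1.29). Another 2 were lower (Alkbh4 −2.27 and Tm9sf1 −1.37), and Prdx2 (−0.18) and Acaa2 (−0.68) did not pass. The mean of the broad probes thus rests much on Actb and on H2-Q7, whose gene is uncertain. Of the 11 restricted probes 9 were lower before cyclic loess, but which class held most of the gap depended on the scaling. Before cyclic loess the means were 1.61 for the 8 broad probes and −2.01 for the restricted probes. After cyclic loess the means were 2.25 and −1.24, so the place of the gap decides nothing. Since the classes were set after the values were seen and hold Actb and Ppara, which mark the pattern, the test is no independent support. Loss of Rnasek itself stays open and cannot be told apart from a difference in preparation or scan, as 0 scans hold both genotypes. Nor can it be told apart from an effect of the active recombinase, which only the KO MEFs carried.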

How the results depend on the processing

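Cyclic loess, all uses of the median spot signal, the crossed block and all settings for the accession probes were chosen after seeing the data, and the rest were planned. The count of circRNAs that differed stayed within 1.5 times of 9229 under all alternatives but the filter for signal on all arrays, which tests fewer probes (5190, with 1511 higher, and 5418 at the unadjusted threshold with 1.5-fold). Set and direction of calls were less stable (cause not tested). The count of higher circRNAs was 1801 after normexp with the 75th percentile, 2634 after normexp with quantile normalization and 3211 in the value table, and the count of lower circRNAs was 1251 without scaling. At the unadjusted threshold the 2 normexp settings gave 4796 and 4057. The median change of 0.44 became −0.13 (quantile), 1.65 (no scaling), −0.26 (median), −0.32 (normexp, 75th percentile) and −0.022 (normexp, quantile). The unscaled shift of 1.65 was 1.67 on median less background signals, 0.33 on normexp values, 0.46 on circRNAs above background on all arrays and 1.41 on all circRNA probes. With 1 array left out, where the lone array is assumed to vary like the other group, 7933 to 8960 circRNAs differed (4711 to 5211 higher, 3222 to 3769 lower), 8329 to 9231 passed the unadjusted threshold, and the unscaled shift was 1.55 to 1.73. The 4 named circRNAs kept direction and call under every setting, but not their size (−2.52 for ASCRP4006290 after normexp with quantile normalization).

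Accession probes higher in KO MEFs numbered 9 after quantile normalization and 9 under each normexp setting, and lower ones 7 without scaling. With 1 array left out, 31 to 33 differed, 14 to 15 higher and 16 to 19 lower. The log2 change reversed for Gsta4 (−0.31), Cep41 (−0.22), Bambi (−0.40), Trp53rka (−0.46) and Carhsp1 (−0.24) after normexp with the 75th percentile, for Bambi (−0.020), Trp53rka (−0.0043) and Ascl1 (0.25) after normexp with quantile normalization, for Trp53rka (−0.13), Carhsp1 (−0.034) and Ascl1 (0.33) after quantile normalization, for Carhsp1 (−0.46), Apoe (0.53), Ascl1 (1.04) and Lhx1 (0.22) after cyclic loess, and for Apoe (0.12) without scaling. Of these, Bambi and Trp53rka after normexp with the 75th percentile and Ascl1 after cyclic loess were called in the opposite direction. Calls were lost with the direction kept in 43 combinations of gene and setting, over 19 genes.

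The labels share replicate numbers between the groups without saying that they pair samples, and same-numbered samples deviated in opposite directions (r = −0.32 across probes). The replicate block gave 8541 circRNAs, 5110 higher and 3431 lower, and 32 accession probes, and left the unscaled shift at 1.65. The crossed pairing gave 9490 circRNAs, 5510 higher and 3980 lower. Planned but not run were the scan as a block (each scan holds 1 group), the shift relative to spike-in probes (not all of them were well above background on every array), normexp on the mean signal and the host gene lists. Low signal over background on the control arrays limits the dim circRNAs, whose changes are bounds.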

Other observations

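In this part the correlation after cyclic loess was fixed before its result was seen, and the first correlation was chosen after. The replicates of a group also differed along the axis that separates the groups. Across the 12181 circRNA probes, which are not independent replicates, control 2 minus control 1 correlated with KO minus control at r = 0.63, and Rnasek KO 2 minus Rnasek KO 1 at r = −0.65, so control 2 and Rnasek KO 2 lay nearer to the other group. Noise in 1 control array alone could give at most r = 0.14, from the SD of 0.61 between the control arrays and of 2.24 for the change. A trend of the change with signal level is argued against, since r was again 0.63 after cyclic loess (0.67 and 0.83 over the 7396 circRNAs well above background on all arrays). Whatever varied between arrays of one genotype may also contribute to the difference between the genotypes, which stays open.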
